A study of Oryza sativa with 6 samples.

How the data were processed

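Roots of wild-type rice (Oryza sativa) grown in a greenhouse (12 h light at 30 °C, 12 h dark at 28 °C) were compared under 10 µM cadmium (Cd) with and without 0.5% Fo10. The labels do not say what Fo10 is. They give 3 libraries of roots under Cd alone (Cd) and 3 of roots under Cd with Fo10 (Fo+Cd). No group without Cd is among the samples, so an effect of Cd itself was not tested. Per the labels' protocols, total RNA was extracted with TRIzol and 1 µg was made into stranded, poly(A)-selected Illumina libraries. The aligner, the counting program and the genome build are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

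The authors deposited one table of TPM values (transcripts scaled to a fixed total per library) for 42031 features: 40745 rice gene models with indica-type identifiers and 1286 noncoding RNA features. TPM was recognised from the values, which have 2 decimals and sum to 963281 to 966767 in each library. The listed features therefore hold 96.3% to 96.7% of the TPM scale. A further column per group held the authors' mean of the 3 libraries (largest difference 3.3e-07 TPM, tolerance 0.000001) and was not used. TPM keeps no record of depth: the number of reads behind each value is unknown, and no counting intervals or detection floors were computed. A total of 13438 features were listed at 0 in all 6 libraries. No pair of libraries shared more than 1.23% identical values among features above 0 in both, so none was treated as a duplicate.

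The design drawn up before the data were examined allowed for counts or for normalized values, and the branch for normalized values was used. Values were transformed to log2(TPM + 1), and features with at least 1 TPM in at least 3 libraries were kept. Fo+Cd was tested against Cd in all 6 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings, no covariate). P-values were adjusted by the Benjamini-Hochberg method, and a feature was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of genes near 1 TPM. In 5 simulated sets with the measured means and spreads, run on 20884 genes with 100 changed per fold size, the test recovered 76.4% of genes changed 2-fold and 95.0% of those changed 4-fold for this comparison. It made 11.6 false calls per set. A further small group of genes, raised 2-fold to try the set test, was left out of both counts. The changed genes counted for recovery were drawn only from genes well above the filter at 1 TPM, so recovery near the filter was not measured. Noise was drawn separately for each gene, so genes that vary together were not simulated. Library-level values were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

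Gene lists were fixed before the data were examined: 21 lists of 228 entries by rice locus identifier and 19 by patterns in the gene descriptions. The table uses another type of identifier. Members were therefore matched, before any test was run, by the rice locus identifier quoted in a description (17 entries), by gene name, or by the class named in a description. This departs from the original rule, which took locus identifiers alone, also for the genes named. In all, 83 entries (80 genes) were matched. Matched genes described without a database source were kept in the locus lists. Nearly all such genes were called, so which entries could be matched may have depended on the outcome. Aquaporins had no matched entry, and no description matched the pattern for glucan endo-1,3-beta-glucosidases, so neither list has a result. Lists with at least 3 tested members were tested with limma's camera (preset inter-gene correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over 26 lists. Camera with an estimated correlation and limma's rotation test fry were alternatives. Camera compares a list with the other genes, whereas fry asks whether its members moved on balance in one direction, so a fry value does not decide a camera call.

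An exploratory fit of the genes, with the same settings as the one reported, was run and looked at before the set tests were set up. It showed that nearly all genes described without a database source were called. The lists made from descriptions were then limited to descriptions that cite a database, a choice made after seeing those calls that departs from the plain pattern match of the design. With the other descriptions added, 14 of 28 lists passed in place of 11 of 26. Of the 26, 12 then passed, and the other 2, germin-like proteins and glutathione S-transferases, reach 3 members only with these genes. Further sets were put together after the gene names had been seen: descriptions shared by at least 8 genes, and named genes of DNA replication, cytokinin response regulators, SWEET and SUT sugar transporters, DREB1 transcription factors, and TIFY and JAZ proteins. The named-gene sets were written down before the exploratory fit, and the description families were set up after it and before any set test. Of these, 65 had at least 5 tested members and were adjusted together; DREB1 had no tested member. A last group of 4 lists (plastid isoprenoid pathway, tryptophan and serotonin synthesis, glutathione S-transferases by name or description, methionine salvage) was chosen because called genes belonged to them, so their p-values are not independent evidence.

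The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes described as a known kind of protein with an adjusted p under 0.05, a change of at least 2-fold, at least 10 TPM in the higher group and no overlap between groups. From each fixed list it took up to 4 called members with the smallest adjusted p, or up to 2 members with the smallest p, given as values, where none was called. It also took 8 cadmium and metal transport genes whatever their result; of these OsHMA3 alone was matched, and OsNRAMP5, OsNRAMP1, OsHMA2, OsIRT1, OsLCT1, OsCd1 and OsPCS1 were not analysed here. Any other gene named in the text was chosen after its values were seen or is a further member of a list under discussion. No genome of the table's build was used, so no coordinates are given.

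Alternatives fixed before the data were examined were quantile normalization, centring on the median gene, no filter, a filter at 5 TPM, a pseudocount of 0.1, limma without trend, the replicate number as a block, leaving out each library in turn, and an added 2-fold threshold. The limma-voom alternative is for counts and was not run. Leaving out noncoding features, leaving out list members described without a database source, and adding genes so described were alternatives chosen after seeing the data.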

Results

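Expression was measured by RNA sequencing in 6 libraries from rice roots, 3 under 10 µM Cd (Cd) and 3 under 10 µM Cd with 0.5% Fo10 (Fo+Cd). The values were the authors' TPM, and the depth behind them is unknown. Between 24954 and 25793 features were above 0 in a library, and 20861 to 21126 reached 1 TPM. The 10 most abundant features held 5.33% ± 0.382 of the TPM in Cd and 5.04% ± 0.749 in Fo+Cd (SD, n = 3 each, exact permutation p = 0.6, two-sided). Photosynthesis transcripts, a marker of shoot tissue, held 0.00272% ± 0.000116 and 0.00308% ± 0.000529 (exact permutation p = 0.4). Over 9 such library-level measures the smallest exact permutation p was 0.2 (adjusted p = 0.9); the smallest this design allows is 0.1, so none of them could have passed 0.05. Correlations of log2(TPM + 1) were 0.957 to 0.977 within groups and 0.942 to 0.954 between groups. The first principal component held 40.6% of the variance.

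The comparison asked which root transcripts differ when Fo10 is given with Cd. Of 5 tested genes of diterpenoid phytoalexin synthesis 4 rose with Fo10, led by OsCPS2 (0.64 ± 1.09 to 42.4 ± 3.33 TPM, SD, n = 3). Among the Cd libraries, all 5 were highest in Cd replicate 3, as were most of the 10 largest rises given below. Of the 2 with a database-sourced description 1 rose. The other 3 risers are described without a database source, a class of genes called 206 times of 226. The pathogenesis-related gene PBZ1, also so described, rose from 156 to 1045 TPM. Of 114 class III peroxidases 9 fell and 2 rose, and the glutathione S-transferase gene GSTU5, again without a source, fell from 126 to 30.7 TPM. Of 21166 features tested, 518 were called by limma (adjusted p under 0.05), 365 higher and 153 lower in Fo+Cd. At least a 2-fold change was seen for 253 of the higher and 63 of the lower features. Unadjusted, 3262 features had p under 0.05. The groups did not overlap in any of the 518, against 21.3% of all tested features and 10% expected by chance. Calling favours features whose groups are apart, so this is not added support for the calls. The number of calls was 310 without Cd replicate 1, 726 without Cd replicate 2, 240 without Cd replicate 3, and 269, 253 and 189 without Fo+Cd replicates 1, 2 and 3. Without Cd replicate 2 the called features divided into 367 higher and 359 lower, against 70.5% higher with all libraries.

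**Figure D1:**
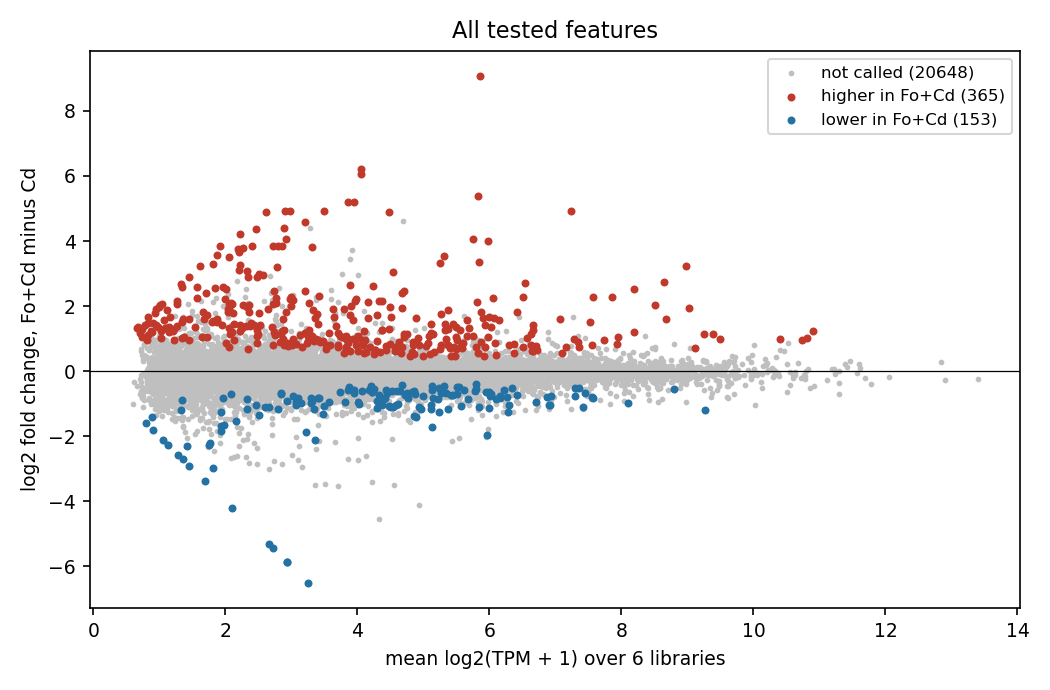
Each point is one of the tested features, with the mean log2(TPM + 1) over 6 libraries on the horizontal axis and the log2 fold change of Fo+Cd over Cd on the vertical axis. The 365 features called higher (red) reach larger changes than most of the 153 called lower (blue), and grey points were not called.

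A property of the table bears on every named gene. Of the gene models, 5312 have a description that cites a database and 230 have one that does not. Of the tested genes described without a source, 206 of 226 were called (190 higher, 16 lower), against 94 of 4288 with a sourced description and 205 of 16550 with none. Such a description is therefore not independent evidence for the direction of a gene, and it is marked below. It applies to 8 of the 10 largest rises and 5 of the 10 largest falls among the described protein genes eligible to be named. A further 15 higher and 12 lower genes met the same criteria but had no description and are not named.

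Among called protein genes with a description and at least 10 TPM in the higher group, the largest log2 rise was that of BGIOSGA033924, described as a leucine-rich repeat extracellular glycoprotein precursor, from 1.08 ± 0.95 to 143 ± 13.9 TPM (SD, n = 3; log2 fold change 6.23, SE 0.341, adjusted p = 0.000483). An isoflavone reductase homolog (BGIOSGA002047) rose from 1.09 ± 0.502 to 135 ± 8.29 TPM (log2 fold change 6.06, SE 0.188, adjusted p = 3.2e-05). A gene described as the LRR receptor kinase BAK1 (BGIOSGA033927) rose from 8.38 ± 3.68 to 368 ± 26.9 TPM. FAD2-2 (BGIOSGA025568), a fatty acid desaturase, rose from 1.55 ± 1.17 to 86.5 ± 4.51 TPM. A pathogenesis-related protein of the Bet v I family (BGIOSGA037574) went from 33.4 ± 29.6 to 837 ± 61.6 TPM. In Cd replicates 1, 2 and 3 it was at 15.8, 16.8 and 67.6 TPM. Its call was lost without any one of the Fo+Cd replicates (adjusted p = 0.052, 0.0687 and 0.0514). The other rises of this group were a terpene synthase (BGIOSGA008467, log2 fold change 4.93), a blight-associated p12-like protein (BGIOSGA020644, 4.92), OsCPS2 (BGIOSGA008469, 4.92), DXS (BGIOSGA025304, 4.89) and Adh3 (BGIOSGA034308, 4.40). Of these 10, OsCPS2 and Adh3 have a sourced description. Adh3, of the alcohol dehydrogenase family, rose from 0.617 ± 0.235 to 33.2 ± 5.87 TPM.

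The falls among such genes were smaller. The tau-class glutathione S-transferase gene GSTU5 (BGIOSGA029891) fell from 126 ± 32.3 to 30.7 ± 4.05 TPM (log2 fold change -1.98, SE 0.204, adjusted p = 0.00467), and GSTU8 (BGIOSGA033325) from 47.9 ± 5.18 to 17.3 ± 2.77 TPM; both are described without a source. GSTU33 (BGIOSGA033328) fell from 942 ± 186 to 409 ± 64.4 TPM, a call that was lost without Cd replicate 3 or any Fo+Cd replicate (adjusted p 0.0617 to 0.0797). The peroxidases in this group were prx46 (BGIOSGA012711, log2 fold change -1.72), prx130 (BGIOSGA034670, -1.18) and BGIOSGA012714 (-1.17), all with a sourced description. A ubiquinol oxidase gene (BGIOSGA008063) fell from 119 ± 2.7 to 49.3 ± 5.23 TPM (log2 fold change -1.26, adjusted p = 0.000947). It is 1 of 4 tested genes so described, and the other 3 were not called. The remaining falls, all described without a source, were OsSAR1 (BGIOSGA022571, -1.38), UNP1 (BGIOSGA014301, -1.31) and a haloacid dehalogenase-like hydrolase (BGIOSGA033472, -1.13). OsSAR1 lost its call without Cd replicate 3 and Fo+Cd replicates 1 and 2 (adjusted p 0.0524 to 0.0653), and UNP1 without Fo+Cd replicate 3 (0.0608).

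**Figure D2:**
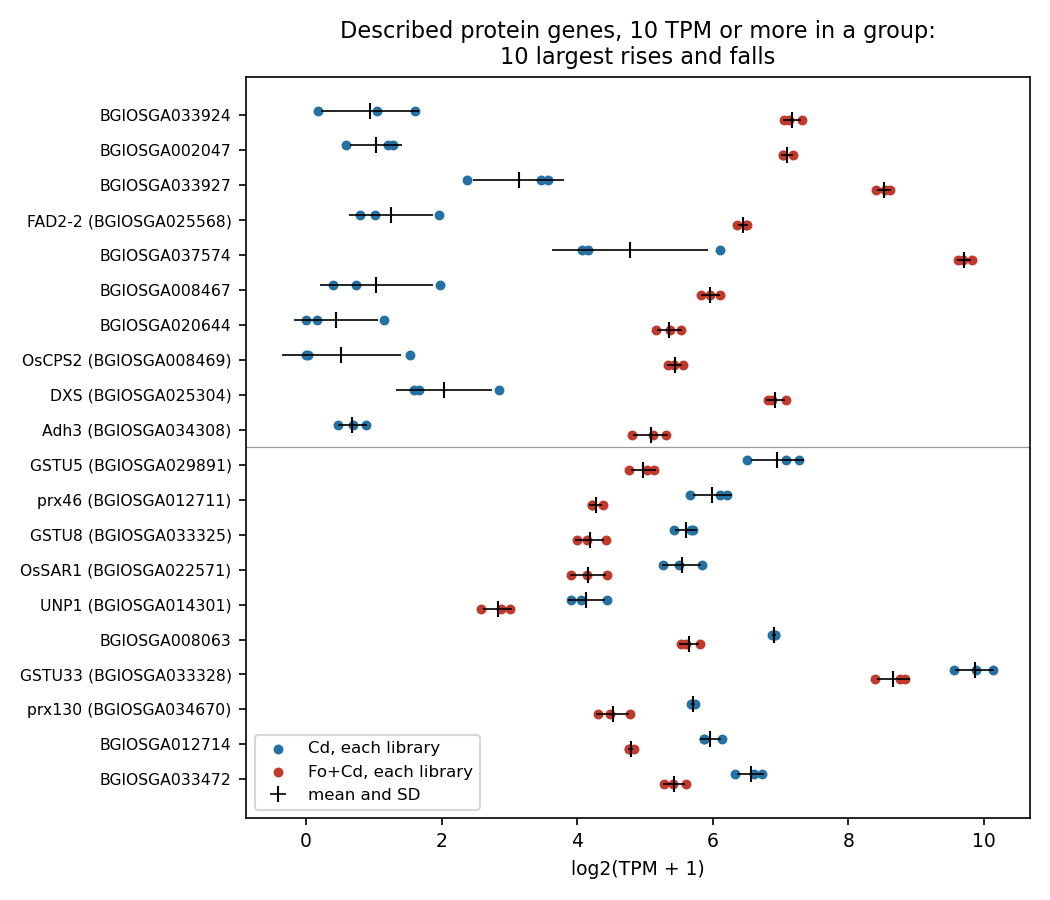
Each point is the log2(TPM + 1) of 1 library for the described protein genes at 10 TPM or more in a group with the largest log2 rises (above the grey line) and falls (below it), in Cd (blue) and Fo+Cd (red), with black ticks and bars for the mean and SD of 3 libraries. The groups do not overlap for any of these genes, since that was a condition for naming them; GSTU5, the largest log2 fall among them, went from 126 to 30.7 TPM.

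Among the fixed lists, diterpenoid phytoalexin synthesis had the largest change. These enzymes make the antimicrobial diterpenes of rice. Of its 5 tested members, 4 rose and 1 did not pass, and 5 passed when adjusted over the list alone (camera adjusted p = 4.67e-10; adjusted p = 0.235 with an estimated correlation). OsCPS2, an ent-copalyl diphosphate synthase, rose from 0.64 ± 1.09 to 42.4 ± 3.33 TPM (adjusted p = 0.00234). Its Cd values were 0.02, 0 and 1.9 TPM in replicates 1, 2 and 3. Among the Cd libraries, all 5 members were highest in Cd replicate 3. This was not particular to the list: of the 10 largest rises, all but Adh3 and BGIOSGA002047 were also highest there. These rises may therefore not be separate pieces of evidence. CYP99A3 (BGIOSGA015981), a P450 of momilactone synthesis, rose from 15.1 ± 4.55 to 253 ± 16.5 TPM. OsCPS4 (BGIOSGA015502) rose from 11.8 ± 6.85 to 135 ± 11.7 TPM, and CYP76M8 (BGIOSGA008465) from 0.583 ± 0.65 to 13.4 ± 0.212 TPM. OsKSL4 (BGIOSGA015980) was at 1.17 ± 1.62 and 8.51 ± 2.05 TPM (adjusted p = 0.0729). CYP99A3, CYP76M8 and OsCPS4 are described without a source, so the set p rests largely on such genes. Their place among the matched members may have followed from their being called, so neither the set p nor the share that rose is independent of the calls. The 2 sourced members, OsCPS2 and OsKSL4, are too few for a set test. The 8 cytochrome P450s with a sourced description also stood above other genes (camera adjusted p = 0.000717; 0.235 with an estimated correlation). One of them, CYP76M5 (BGIOSGA008463), was called (from 0.317 ± 0.289 to 17.0 ± 1.34 TPM), and 4 passed when adjusted over the list alone. A further 7 described without a source, CYP76M8 among them, were all called higher (log2 fold change 1.22 to 3.74). Reads may be shared between members of these families, so the values of single members are uncertain.

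Of 6 defence proteins and regulators, 1 rose: PBZ1 (BGIOSGA037571), a PR10-type protein described without a source, went from 156 ± 34.4 to 1045 ± 141 TPM (adjusted p = 0.000483). Adjusted over the list alone, 1 member was higher and 1 lower. The list as a whole did not pass (camera adjusted p = 0.408, direction down, median log2 fold change -0.28, mean 0.12). Without PBZ1 it passed in the downward direction (adjusted p = 0.0323; 0.372 with an estimated correlation). Of 24 WRKY transcription factors, 21 were tested. WRKY72 (BGIOSGA035289) rose (log2 fold change 1.02), and WRKY58 (BGIOSGA017690, -1.05), WRKY74 (BGIOSGA030535, -0.55) and the WRKY 45-2 gene (BGIOSGA019621, -0.59) fell; 5 passed when adjusted over the list alone. One more, described without a source and outside the list, was called higher (1.44). WRKY58 lost its call without Cd replicate 2 or 3 or Fo+Cd replicate 1 or 3 (adjusted p 0.0524 to 0.105), BGIOSGA030535 without any one library but Cd replicate 1 (0.0813 to 0.171), and BGIOSGA019621 without any one library (0.0507 to 0.166). The set test missed the threshold (camera adjusted p = 0.0851) but passed without Cd replicate 1, Fo+Cd replicate 2 or Fo+Cd replicate 3 (0.0401, 0.0205 and 0.0335). Jasmonate synthesis and JAZ repressors had 1 riser of 8, OsAOS2 (BGIOSGA012156), an allene oxide synthase described without a source (from 9.04 ± 2.29 to 43.0 ± 4.16 TPM). Adjusted over the list alone 3 passed, 2 higher and 1 lower; the set test gave an adjusted p of 0.699, with a negative median (-0.28) and mean (-0.06). None of 6 phenylalanine ammonia-lyases, the entry enzymes of phenylpropanoid synthesis, passed in limma over all genes or adjusted over the list alone (2 with unadjusted p under 0.05; set adjusted p = 0.601, direction down, median 0.06, mean -0.04). The 2 with the smallest p were BGIOSGA006000 (336 ± 23.7 and 279 ± 25.3 TPM) and BGIOSGA014703 (27.5 ± 0.933 and 21.7 ± 3.89 TPM). Chitinases had 1 higher (BGIOSGA006087, log2 fold change 0.72) and 1 lower (Cht11, BGIOSGA011782, -1.54) of 4, the same number adjusted over the list alone, and a set adjusted p of 0.685. BGIOSGA006087 lost its call without any one library (adjusted p 0.0671 to 0.157), and Cht11 without any one but Cd replicate 2 (0.0731 to 0.0864).

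Of 6 members of the cadmium uptake and transport list, 3 rose, all described without a source. OsABCG43 (BGIOSGA025831), an ABC transporter, rose from 10.5 ± 3.82 to 57.5 ± 4.09 TPM (adjusted p = 0.0023). OsABCC9 (BGIOSGA015573) rose by a log2 fold change of 1.19 from 6.97 ± 1.61 TPM (adjusted p = 0.0132), and OsIRT2 (BGIOSGA010094), an iron-regulated transporter, from 5.03 ± 0.939 to 12.0 ± 2.26 TPM. OsABCC9 lost its call without any one Fo+Cd replicate (adjusted p 0.0536 to 0.0711), and OsIRT2 without any one library except Cd replicate 2 (0.0576 to 0.097). OsHMA3 (BGIOSGA024568), which moves Cd into root vacuoles, was at 9.41 ± 1.56 in Cd and 7.91 ± 1.28 TPM in Fo+Cd (log2 fold change -0.22, adjusted p = 0.574). Adjusted over the list alone, 4 members were higher. The set test passed (camera adjusted p = 0.00103; 0.235 with an estimated correlation), but not for the 3 members with a sourced description (adjusted p = 0.573). In iron acquisition, OsIRT2 was the 1 member called of 7, and 5 were higher when adjusted over the list alone (camera adjusted p = 0.00103; 0.291 with an estimated correlation; 0.0527 with fry). OsYSL15 (BGIOSGA005930), which takes up iron bound to phytosiderophores, was at 100.3 ± 24.1 and 172 ± 21.6 TPM (adjusted p = 0.0783).

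No metallothionein was called among 6 in limma, over all genes or adjusted over the list alone (1 with unadjusted p under 0.05; set adjusted p = 0.353). MT2C (BGIOSGA019039) was at 54.7 ± 4.48 and 38.2 ± 8.21 TPM, and the abundant BGIOSGA035979, a type 1 gene, at 6669 ± 526 and 8126 ± 1595 TPM. For zinc, manganese, copper and silicon transport, 0 of 3 were called (1 with unadjusted p under 0.05, none adjusted over the list alone, set adjusted p = 0.133); without Fo+Cd replicate 1 the set adjusted p was 0.0289. OsHMA4 (BGIOSGA007732) was at 67.9 ± 4.64 and 83.0 ± 7.82 TPM, and OsLsi2 (BGIOSGA011605) at 715 ± 106 and 904 ± 199 TPM. Of 6 metal transporters found by description, a zinc transporter (BGIOSGA025423) was higher, at 99.1 ± 4.74 against 67.2 ± 4.17 TPM (adjusted p = 0.0214). It was also the 1 member adjusted over the list alone, the set adjusted p was 0.273, and its call was lost without Cd replicate 1 or 3 or Fo+Cd replicate 2 or 3 (0.0525 to 0.115). Of 16 ABC transporters with a sourced description, 0 were called, also adjusted over the list alone (4 with unadjusted p under 0.05; set adjusted p = 0.273). A further 5 described without a source, OsABCG43 and OsABCC9 among them, were all called higher (log2 fold change 0.98 to 2.39), and with them added the set passed (adjusted p = 0.000303). Among the 16, the smallest p belonged to OsABCG36 (BGIOSGA001233, 16.6 ± 3.92 and 33.1 ± 10.1 TPM) and BGIOSGA013583 (44.7 ± 2.25 and 53.6 ± 1.61 TPM). Neither of the ferritins of iron storage was called (BGIOSGA036792, log2 fold change 0.41, adjusted p = 0.226, and BGIOSGA034644, -0.15, adjusted p = 0.594), while 1 had an unadjusted p under 0.05 and was higher adjusted over the list alone.

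Of 114 class III peroxidases, 9 fell and 2 rose (camera adjusted p = 1.64e-05, median log2 fold change -0.20; adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone, 20 were lower and 5 higher. The smallest adjusted p values belonged to BGIOSGA012714, prx46 and prx130, given above, and to BGIOSGA003401, which rose from 4.97 ± 1.26 to 17.1 ± 0.586 TPM. Of 24 xyloglucan endotransglucosylases, which remodel wall glucans, 2 fell (BGIOSGA027399, log2 fold change -1.84, and BGIOSGA022835, -0.74) and 6 were lower adjusted over the list alone (camera adjusted p = 0.00111; 0.235 with an estimated correlation). BGIOSGA027399 lost its call without Cd replicate 1 or 3 or Fo+Cd replicate 2 (adjusted p 0.0512 to 0.0574), and BGIOSGA022835 without any one library but Fo+Cd replicate 1 (0.0758 to 0.141). Of 5 expansins, 1 fell, EXPA4 (BGIOSGA017864, from 40.5 ± 1.64 to 23.6 ± 2.36 TPM), and 2 were lower adjusted over the list alone (camera adjusted p = 0.0113; 0.235 with an estimated correlation). EXPA4 had an adjusted p of 0.0516 without Cd replicate 3. Among 29 dirigent proteins, which guide phenoxy radical coupling, BGIOSGA024968 rose (log2 fold change 1.08), while the list stood below other genes (camera adjusted p = 0.0306; 0.413 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone). The call on this list was lost without Cd replicate 3, Fo+Cd replicate 1 or Fo+Cd replicate 2 (0.229, 0.114 and 0.061); fry gave 0.243. Of 8 laccases, LAC19 (BGIOSGA021910, log2 fold change 2.16) and BGIOSGA019394 (0.65) were higher and BGIOSGA019397 (-0.69) lower; 2 were higher and 2 lower adjusted over the list alone. The laccase set adjusted p was 0.713, its direction down, its median -0.22 and its mean 0.12. BGIOSGA019394 lost its call without any one library (adjusted p 0.0592 to 0.174), and BGIOSGA019397 without any one but Cd replicate 2 (0.0568 to 0.0805).

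Of 7 antioxidant enzymes, the catalase OsCATA (BGIOSGA007252) rose from 31.6 ± 3.82 to 80.9 ± 10.9 TPM (adjusted p = 0.00296), and 3 were higher adjusted over the list alone. The list passed (camera adjusted p = 0.0306; 0.238 with an estimated correlation) but not without Cd replicate 1 or Fo+Cd replicate 2 (0.0739 and 0.098). In the low oxygen list, OsHB1 (BGIOSGA012186), a non-symbiotic haemoglobin, rose from 15.9 ± 3.07 to 52.7 ± 14.9 TPM as the 1 member called of 4, over all genes and adjusted over the list alone. This call was lost without any one library except Cd replicate 2 and Fo+Cd replicate 2 (adjusted p 0.0672 to 0.0923) and with the replicate number as a block (0.0995). The list passed (camera adjusted p = 0.0143; 0.328 with an estimated correlation; 0.0778 with fry; 0.0517 without Fo+Cd replicate 3). Of 6 heat shock proteins found by description, none was called in limma (2 with unadjusted p under 0.05 and higher adjusted over the list alone), and the list passed (camera adjusted p = 0.0306; 0.235 with an estimated correlation). Its call was lost without Cd replicate 2 or Fo+Cd replicate 3 (0.128 and 0.0517). HSP81-1 (BGIOSGA026730) was at 699 ± 50.9 and 960 ± 61.7 TPM, and BGIOSGA036094 at 66.6 ± 6.38 and 88.2 ± 10.6 TPM. OsHSP18.0 (BGIOSGA012296), the 1 matched member of the locus-based heat shock list, was at 91.1 ± 9.98 and 57.3 ± 9.08 TPM (adjusted p = 0.0598), and lower adjusted over the list alone. OsGSH1 (BGIOSGA019114), the 1 matched member for sulfate assimilation, was at 41.3 ± 2.77 and 39.4 ± 3.36 TPM (adjusted p = 0.791, also not passing adjusted over the list alone). Neither of 2 glutathione S-transferases with a sourced pattern match was called over all genes, and both were lower adjusted over the list alone: GSTU1 (BGIOSGA009694, 51.8 ± 9.68 and 30.9 ± 1.48 TPM) and BGIOSGA033329 (839 ± 38.5 and 616 ± 92.5 TPM). The 2 described without a source, GSTU5 and GSTU8, are the falls given above.

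Markers of other tissues and of cell types did not pass over all genes. Of 5 tested photosystem and light-harvesting proteins, 0 were called in limma, over all genes or adjusted over the list alone (0 with unadjusted p under 0.05; set adjusted p = 0.19; 0.0411 without Fo+Cd replicate 3). The leading pair, BGIOSGA035064 and BGIOSGA030566, reached 8.14 ± 1.94 and 7.38 ± 1.43 TPM in Fo+Cd, against 5.81 ± 0.0551 and 5.68 ± 1.00 TPM in Cd. Of the leaf photosynthesis markers, the Rubisco small subunit genes were at 1.67 ± 0.894 and 0.987 ± 0.645 TPM (BGIOSGA007558) and at 2.54 ± 0.514 and 2.71 ± 0.400 TPM (BGIOSGA037260). PCNA (BGIOSGA009238), the 1 matched marker of dividing cells, was at 84.2 ± 3.25 and 91.5 ± 22.7 TPM. Of the endodermis and root hair genes, OsCASP1 (BGIOSGA017380) was at 169 ± 12.2 and 144 ± 5.96 TPM, with an unadjusted p under 0.05, and OsLsi2, given above, is the other. None of these 3 lists had a member that passed adjusted over the list alone. The secondary wall genes CESA4 (BGIOSGA004463) and CESA9 (BGIOSGA030777) were at 37.7 ± 5.8 and 27.6 ± 4.42 TPM and at 32.8 ± 8.91 and 23.6 ± 5.18 TPM; 1 was lower adjusted over the list alone. Of 59 cytosolic ribosomal proteins 0 were called, also adjusted over the list alone (1 with unadjusted p under 0.05). Their camera adjusted p was 0.408, and 0.863 with an estimated correlation (0.78 for this list). With the preset correlation, leaving out Fo+Cd replicate 1 gave a downward call (0.0337) and leaving out Fo+Cd replicate 2 an upward one (3.72e-07). The estimated correlation was not used with a library left out. The smallest p belonged to BGIOSGA018220 (log2 fold change 0.32, adjusted p = 0.274) and BGIOSGA021998 (145 ± 23.0 and 192 ± 34.7 TPM). Of 41 histones 0 were called, also adjusted over the list alone (0 with unadjusted p under 0.05). Their camera adjusted p was 0.127, and 0.709 with an estimated correlation. Without Fo+Cd replicate 1 it was 4.39e-05 with the preset correlation. BGIOSGA036274 was at 206 ± 18.6 and 168 ± 23.8 TPM and BGIOSGA021865 at 136 ± 6.23 and 170 ± 32.0 TPM.

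In the remaining lists no listed member was called by limma over all genes. For phosphate starvation (4 tested, 1 with unadjusted p under 0.05 and higher adjusted over the list alone, set adjusted p = 0.43), OsPT4 (BGIOSGA015518) was at 2.67 ± 0.0208 and 4.75 ± 0.913 TPM and OsSPX2 (BGIOSGA007749) at 13.0 ± 1.68 and 12.2 ± 1.15 TPM. For nitrogen uptake, OsNAR2.1 (BGIOSGA006127) was at 85.2 ± 18.5 and 101 ± 6.15 TPM and OsNRT2.3 (BGIOSGA004285) at 28.4 ± 6.76 and 34.1 ± 6.85 TPM (0 with unadjusted p under 0.05 or adjusted over the list alone). For abscisic acid and water deficit, with 0 at an unadjusted p under 0.05 or adjusted over the list alone, OsDREB2A (BGIOSGA002846) was at 22.6 ± 2.95 and 20.8 ± 0.941 TPM and OsLEA3 (BGIOSGA020289) at 36.5 ± 26.1 and 23.6 ± 5.8 TPM. Of 3 Aux/IAA and SAUR genes (1 with unadjusted p under 0.05, none adjusted over the list alone, set adjusted p = 0.273, and 0.0445 without Cd replicate 2), IAA13 (BGIOSGA009837) was at 410 ± 88.5 and 280 ± 20.8 TPM and IAA5 (BGIOSGA004190) at 54.4 ± 15.7 and 39.6 ± 6.69 TPM. Both are described as auxin-responsive proteins. The 27 tested genes with that bare description are outside this list and stood lower (camera adjusted p = 0.0343, and 0.769 with an estimated correlation). A germin-like protein (BGIOSGA028117) was at 271 ± 78.3 and 375 ± 22.2 TPM and passed adjusted over the list alone, in which it is the 1 tested member; 3 more described without a source, outside the list, were all called higher (log2 fold change 1.01 to 2.45). A UDP-glycosyltransferase (BGIOSGA000437) was at 2.65 ± 0.479 and 2.82 ± 0.912 TPM (adjusted p = 0.941, not passing adjusted over the list alone).

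**Figure D3:**
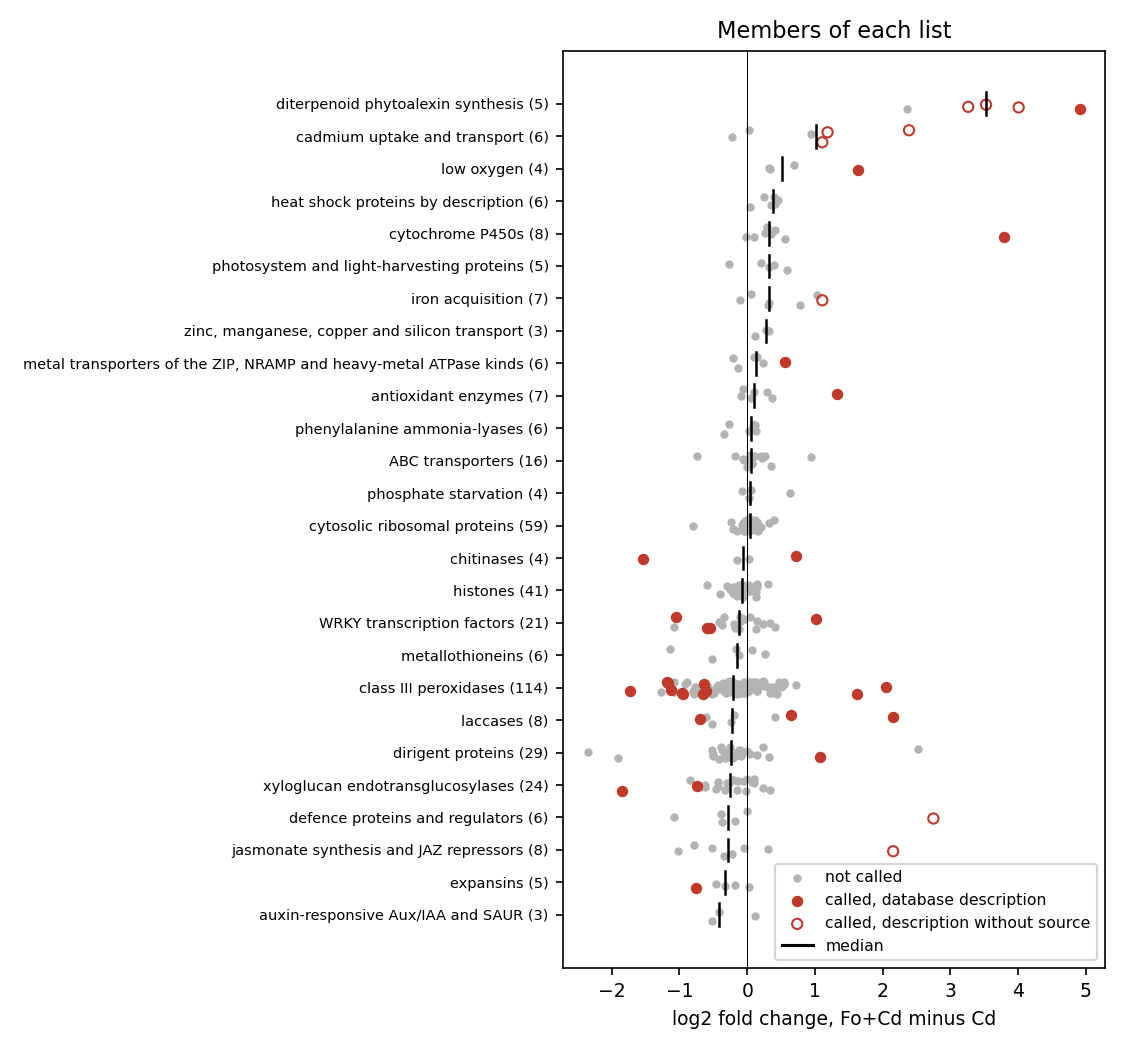
Points are the log2 fold changes of Fo+Cd over Cd for the tested members of the 26 lists with at least 3 of them (number of members in parentheses), and black ticks are the list medians. Filled red points were called and have a database description, open red points were called and are described without a source, and grey points were not called; the median of diterpenoid phytoalexin synthesis is 3.53.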

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

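Leaving out noncoding features, leaving out list members described without a database source, and adding genes so described were tests chosen after the data had been seen. All 46 called named genes kept their direction in the alternatives in which they were tested, and 28 kept their call in all of these. Adh3 and CYP76M5, among the 28, were under 1 TPM in every Cd library. They missed the filter and were not tested when any Fo+Cd replicate was left out. The call was lost by 18 when a library was left out, and by 8 in another alternative: 5 without a filter, 5 without trend, 2 with median centring, 2 with a pseudocount of 0.1, 1 with quantile normalization and 8 with the replicate block. Those lost without a filter were BGIOSGA006087, BGIOSGA019394, BGIOSGA030535, BGIOSGA019621 and BGIOSGA022835, and the same genes were lost without trend. Quantile normalization, median centring, a filter at 5 TPM, a pseudocount of 0.1, limma without trend and leaving out noncoding features gave 509, 498, 484, 460, 466 and 508 calls, against 518. No filter gave 96 lower features in place of 153 with 28593 tested, and the cause was not tested. Requiring a 2-fold change left 316 calls, 63 of them lower. Leaving out 1 library gave 189 to 726 calls, 137 to 367 higher and 26 to 359 lower, and 18 to 36 called members of the fixed lists in place of 37; the cause was not tested.

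The replicate numbers gave no clear sign of pairing the samples, though 3 libraries per group cannot exclude it. Deviations of same-numbered libraries correlated at -0.03, 0.08 and 0.07. Cd replicates 2 and 3 correlated best with the Fo+Cd replicate of the same number, and Cd replicate 1 with Fo+Cd replicate 3 (0.07). With the replicate block 353 features were called, 239 of them higher, and 298 were among the 518. Zinc, manganese, copper and silicon transport then passed (adjusted p = 0.0431), and no other set test changed its call. Of the set tests, 11 passed camera with the preset correlation, 0 with an estimated correlation (5 at unadjusted p under 0.05) and 9 fry. For heat shock proteins by description the estimate (-0.074) lay under the preset 0.01, yet the unadjusted camera p rose from 0.0128 to 0.0632. The other called lists had estimates above 0.01. A call lost with this setting therefore need not reflect correlation between members. With fry, metal transporters by description passed (0.0397), and lists not called turned direction: defence proteins (0.352), jasmonate (0.584) and laccases (0.317). With genes described without a source added, 14 of 28 lists passed: the 11, ABC transporters (0.000303) and 2 lists that reach 3 members only then. With such genes left out, 10 of 25 passed, and diterpenoid phytoalexin synthesis had too few members to be tested.

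Results that turned direction when 1 library was left out had not been called. The log2 fold changes ranged from -0.13 to 0.21 for BGIOSGA000437, -0.78 to 0.12 for OsLEA3, -0.085 to 0.28 for PCNA, -0.057 to 0.15 for RBCS-c (BGIOSGA037260) and -0.12 to 0.0033 for OsGSH1. The set adjusted p ranged from 0.318 to 0.954 for jasmonate, 0.26 to 0.883 for phenylalanine ammonia-lyases, 0.517 to 0.902 for chitinases and 0.517 to 0.958 for laccases. For cytosolic ribosomal proteins it was 3.72e-07 to 0.655, with the downward call at 0.0337; the cause was not tested for any of these. Depth is unknown, so its effect on low values cannot be given.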

Other observations

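The 4 gene lists of the next paragraphs and the tests of the balance of calls and of the isoprenoid genes were chosen after the results had been seen, so the p-values of these lists are not independent evidence. The description families were set up after the gene-level calls, and the tests on noncoding RNA after its calls but before the sums and spreads they measure. Genes of the plastid isoprenoid pathway, which supplies the geranylgeranyl diphosphate used for diterpenes, were higher in Fo+Cd: 7 of 11 tested members were called, 4 of them described without a source (camera adjusted p = 1.24e-12 over 8 such tests; adjusted p = 0.0259 with an estimated correlation). The 7 sourced members gave 4.97e-05 (adjusted p = 0.0354 with an estimated correlation). DXR (BGIOSGA002548) rose from 30.6 ± 5.72 to 110 ± 6.12 TPM (SD, n = 3; limma adjusted p = 0.000779), and the hydroxymethylbutenyl diphosphate synthase BGIOSGA006093 from 34.6 ± 3.52 to 112 ± 4.83 TPM. GGPPS1 (BGIOSGA024015), described without a source, rose from 29.9 ± 5.82 to 146 ± 10.4 TPM. Copies differed in level: DXS (BGIOSGA025304) went from 3.45 ± 2.36 to 121 ± 12.0 TPM, while the DXS-like BGIOSGA018065 was at 10.5 ± 0.495 and 9.63 ± 0.204 TPM. Tryptophan and serotonin synthesis had 7 of 10 members called, all higher and 4 described without a source (camera adjusted p = 2.32e-13; adjusted p = 0.0259 with an estimated correlation, also for the 6 sourced members). The decarboxylase gene TDC1 (BGIOSGA027967), with a sourced description, rose from 6.71 ± 1.08 to 45.7 ± 2.17 TPM. Of the anthranilate synthase genes, OASA2 (BGIOSGA011056), described without a source, rose from 42.7 ± 3.47 to 90.1 ± 1.74 TPM, and ASA1 (BGIOSGA009526) was at 5.35 ± 0.295 and 5.35 ± 0.465 TPM.

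Of 5 glutathione S-transferase genes taken by name or description, 3 fell, 2 of them described without a source (camera adjusted p = 9.41e-08; adjusted p = 0.0458 with an estimated correlation, and 0.0598 for the 3 sourced members). In the methionine salvage cycle 2 of 5 rose, SIP2 (BGIOSGA031909, log2 fold change 1.14) and BGIOSGA035012 (29.1 ± 1.68 to 47.7 ± 0.893 TPM), with a camera adjusted p of 0.000164 (adjusted p = 0.0706 with an estimated correlation). Of 65 description families and named-gene sets, 8 passed camera, 0 with an estimated correlation (4 at unadjusted p under 0.05) and 1 with fry. DETOXIFICATION proteins, a family of multidrug and toxin exporters, stood higher (32 tested, 3 called; camera adjusted p = 8.02e-05; adjusted p = 0.702 with an estimated correlation; 0.0191 with fry). WAT1-related proteins also stood higher (25 tested, 2 called; adjusted p = 0.035; adjusted p = 0.769 with an estimated correlation), as did ammonium transporters (7 tested, 0 called by limma, 4 with unadjusted p under 0.05; adjusted p = 0.043; adjusted p = 0.769 with an estimated correlation). Besides peroxidases and xyloglucan endotransglucosylases, endoglucanases stood lower (14 tested, 1 called; adjusted p = 0.0286; adjusted p = 0.702 with an estimated correlation). So did genes described as glycosyltransferases in the plural (11 tested, 0 called by limma, 5 with unadjusted p under 0.05; adjusted p = 0.0186; adjusted p = 0.702 with an estimated correlation) and auxin-responsive proteins (27 tested, 0 called by limma, 4 with unadjusted p under 0.05; adjusted p = 0.0343; adjusted p = 0.769 with an estimated correlation). DNA replication (9 tested), cytokinin response regulators (10) and TIFY and JAZ proteins (8) had 0 members called by limma, with 0, 0 and 3 at unadjusted p under 0.05 and set adjusted p of 0.415, 0.733 and 0.438. Of 7 SWEET and SUT sugar transporters 1 fell, SWEET1a (BGIOSGA004923, 29.5 ± 7.25 to 13.5 ± 1.99 TPM), and 3 had an unadjusted p under 0.05 and were lower adjusted over the list alone, with a set adjusted p of 0.0857.

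The tests of single genes did not use descriptions. The result for the isoprenoid genes as a list could, however, come from descriptions written for genes already seen to change. This cannot be told apart from a change of the pathway, because the list was made for its called members: the 7 with a sourced description had a median log2 fold change of 0.73, with DXR, BGIOSGA006093 and IspF called (1.83, 1.68 and 1.25) and 4 not called (-0.15 to 0.73). More green tissue would bring photosynthesis transcripts, which held only 0.00308% of the TPM in Fo+Cd. An effect of Fo10 on this pathway stays open and was not tested apart from these genes.

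More features were higher than lower in Fo+Cd. A shift of the scale as the whole account would move features alike. The log2 fold change over all tested features had a median of 0.0025 and an upper quartile of 0.14, under the smallest rise called (0.47). TPM are scaled to near-equal totals and called features are chosen for large changes, so such values were likely in advance. They show that the features did not all move alike, and cannot exclude a smaller shift or one of some features. The balance varied with the library left out: 70.5% of calls were higher with all 6, 50.6% without Cd replicate 2, where lower calls went from 153 to 359 and higher calls from 365 to 367, and 62.5% to 89.2% without each of the others. The 10 splits of the 6 libraries are too few for a share under 0.05: the real one, the 1 split with as many calls, gave 518 and the highest other 4. An effect of Fo10 on the balance itself stays untested.

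Of 13 called noncoding features 6 were listed at 0 in all libraries of a group, against 19 of 505 called gene models. The within-group SD of 100 tested noncoding features was in the median 3.23 times that of gene models of like mean, as would be seen if noisier values gave these calls. The spread of the 13 called features was not compared separately, so this ratio does not settle why they were called. Feature lengths were not examined, so the noise was not tied to short features. Reads moving between near-identical copies cannot be told apart from a change of the RNA. The summed TPM changed by less than 1.5 times in 33.3% of the kinds with several features. Among these, small subunit rRNA had 5 features called higher, yet its sum was 12623 ± 2061 in Cd and 10075 ± 965 TPM in Fo+Cd. By contrast, the sum of 5.8S rRNA went from 3250 ± 209 to 6682 ± 1261 TPM and that of SNORD14 from 468 ± 190 to 26.4 ± 7.53 TPM. The called U6atac copy was at 0 in all Fo+Cd libraries, while its other copy was at 50.1 TPM in Fo+Cd replicate 3 and at 0 elsewhere. The libraries were poly(A)-selected, so these values may not measure the amount of such RNA in the roots.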
